A study of Mus musculus with 2 samples.

How the data were processed

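ATAC-seq peak lists of 2 biological replicates of mouse blood monocytes were used, on assembly mm10 per the labels. Both samples belong to 1 group, and the replicate numbers are those of the labels. Mice were 5 to 6 weeks old, and the size range of the library was 153 to 309 bp for replicate 1 and 156 to 312 bp for replicate 2, per the labels. The aligner, the peak caller, their versions and the shift of reads for Tn5 are not given in the sources used here.

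The authors deposited peaks called per replicate and peaks made from both replicates, per the deposited README. The README names a further input to the peak sets without saying what it is. Each peak's fold enrichment, a linear ratio over background, is the authors' own value in the deposited lists and was not scaled between samples here. The −log10 p of each peak is also as deposited by the authors. The IDR score, from the authors' ranked lists, measures how well a peak's rank is kept between replicates or pseudoreplicates, and the deposited thresholded sets hold no score under 540. Fold and p describe a peak within its list. No read counts were used, so the depth of each library is unknown, and the number of peaks in a set can move with it.

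The main set was the authors' conservative IDR-thresholded set of the series. For comparisons of the replicates their own pseudoreplicated sets were used, and for calls of gene lists and motifs their own IDR-thresholded sets. Replicate folds at named genes are from the looser pseudoreplicated sets, and replicate counts of distal regions from the thresholded sets. Only chromosomes 1 to 19, X and Y were used. Overlapping peaks were merged into regions with the highest fold and the summit of the smallest p. Gene models were those of GENCODE M21 and sequence that of GRCm38.p6, and 0 peaks ran past the end of their chromosome there. A promoter region lies within 1 kb of a protein-coding TSS, the start of a protein-coding transcript of a protein-coding gene. A distal region lies farther from every such TSS and was assigned to the nearest TSS within 100 kb. Random placements (100) kept chromosome and width.

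A list's mean was compared with 10000 random lists of protein-coding genes, matched in 20 bins on the length of the regulatory domain, or for promoters on the CpG ratio within 500 bp of the TSS. The share is two-sided, adjusted by Benjamini-Hochberg over 29 lists. Random lists were not matched on position in the genome. Some lists hold neighbouring genes, such as Hoxb6, Hoxb8 and Hoxb9, or Ccl6 and Ccl9. The shares treat such genes as separate and may be too small for these lists. A list was called where the adjusted share was under 0.05 and the direction was the same in each replicate's own set. Of the listed genes, 5 were not annotated as protein-coding and were left out. On simulated data with lists of 28 among 21839 genes, 2 of 100 unchanged lists, 22 of 100 lists raised 1.5 times and 51 of 100 raised 2 times passed an unadjusted 0.05, so modest differences are often missed. The simulated lists were drawn at random from all these genes, so they do not test lists of neighbouring genes. Motif ratios compare 100 bp each side of the summit with the mean of windows of equal size 500 bp to each side, with 1000 bootstrap draws over regions.

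Gene lists, motif strings, tests, alternatives and the rule for named genes were set before the data were examined. The design named the replicates' columns in the series-level ranked list for the correlation; these carry no name, so the replicates' own sets were used. The design did not say how to count motifs, and the count of intervals above 1 was settled after the ratios had been seen. Genes named were 35 fixed ones, a few of which are not reported here, the 15 with most distal regions among those in the top 100 of each replicate, the 10 with the strongest promoter peak by mean rank, and of each list the 3 members with most distal regions and up to 2 with no region. The alternatives were other peak sets, each replicate's set alone, other windows, overlaps and distances, no matching, and other motif backgrounds. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.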

Results

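Open chromatin was measured by ATAC-seq in monocytes from the peripheral blood of adult C57BL/6J mice. ATAC-seq inserts sequencing adapters with the Tn5 transposase, which cuts DNA where it is not covered by nucleosomes. The series held 1 group of 2 biological replicates, each made from 50000 cells, and no control group. The labels give the replicates the same donor identifier and do not say whether they came from separate animals, so the spread between them may be technical. The deposited values were lists of peaks, each with a fold enrichment and a −log10 p. The depth of each library is unknown, because no read counts were given, and no interval or detection floor that needs a count is printed.

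The first question was how much of the genome was open. The conservative set, which the authors made from both replicates, held 39944 peaks that merged into 28438 open regions. These regions had a median width of 448 bp (quartiles 321 and 654 bp), covered 14.8 Mb and made up 0.542% of the genome. Their median fold enrichment was 6.49, with quartiles of 5.16 and 8.44. Replicate 1 alone had 17604 regions in its own thresholded set and replicate 2 had 18057. The replicated set of the series, with a looser rule, held 55857 regions, so the count depends on the rule by which peaks were kept.

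The comparison that the design implies is between the replicates. Each replicate's regions were ranked by −log10 p and parted into 4 classes of equal size. Of the strongest class, 9886 of 9894 replicate 1 regions (99.9%) overlapped a replicate 2 region, and 9970 of 9971 replicate 2 regions overlapped a replicate 1 region. In the weakest class the shares were 43.8% and 41.2%. Over all regions, 79.0% of the 39579 regions of replicate 1 were found in replicate 2, and 78.2% of the 39886 regions of replicate 2 were found in replicate 1. When the regions of replicate 1 were placed at random within their chromosomes, 1.31% on average overlapped a replicate 2 region, and the highest of 100 placements gave 1.41%. Regions within 1 kb of a transcription start site (TSS) were shared more often, at 91.2% and 88.3%, than distal regions, at 73.2% and 73.3%. Such regions also made up more of the strongest class, 60.6% and 62.7%, than of the weakest, 19.9% and 20.6%. Sharing near a TSS and away from it was not compared at equal strength. Regions called in replicate 1 alone had a median fold enrichment of 3.87, against 5.85 for its shared regions. In replicate 2 these medians were 3.68 and 5.71.

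**Figure D1:**
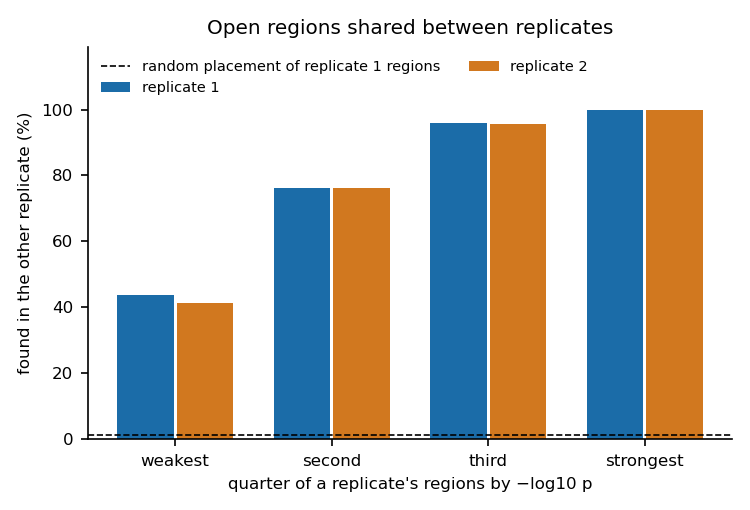
Bars give the percent of a replicate's open regions that overlap a region of the other replicate, in 4 classes of −log10 p, for replicate 1 (blue) and replicate 2 (orange); the dashed line is the mean of random placements, 1.31%. The shares are 43.8% and 41.2% in the weakest class, and 99.9% for replicate 1 in the strongest.

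At the 31273 shared sites the fold enrichments of the replicates had a Pearson correlation of 0.835 on the log2 scale and a Spearman correlation of 0.826. These are correlations across sites, which are not independent replicates, and no p-value was computed. The log2 fold of replicate 2 minus that of replicate 1 had a median of -0.02 and an SD of 0.31, and 0.675% of shared sites lay over 1 log2 unit apart.

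The next question was where the open regions lay. Of the 28438 regions, 10589 (37.2%) lay within 1 kb of the TSS of a protein-coding gene, against 3.22% of regions placed at random, a ratio of 11.5. Introns held 7871 regions (27.7%, against 35.2% at random) and intergenic sequence held 9074 (31.9%, against 58.4%). Exons outside promoters held 904 regions (3.18%), close to the random share of 3.14%. All these shares are of the 28438 regions, so the excess at promoters lowers those of the other classes. They do not tell whether exons or introns were over- or under-represented among regions outside promoters. In the replicates' own thresholded sets the promoter share was 47.6% ± 0.482 (SD, n = 2). Promoter regions were wider than intronic ones, with median widths of 632 and 376 bp, and had a median fold enrichment of 7.64 against 5.95. The promoter share moved with the peak set, as the looser replicated set gave 26.9%.

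Of 21853 protein-coding genes, 10174 (46.6%) had an open promoter. When genes were ranked by promoter CpG ratio and parted into 5 classes of equal size, the share was 77.9% in the richest class and 5.38% in the poorest. The replicates' own thresholded sets opened 8578 and 8896 promoters, of which 8109 were in both. By mean rank over both replicates, the strongest promoter peak was that of Snupn, which encodes the import receptor of spliceosomal snRNPs, with a fold enrichment of 16.9 ± 0.687 (SD, n = 2). Golph3l had 17.4 ± 2.15, Pigu 16.7 ± 1.05, Prpf8, a core protein of the spliceosome, 16.6 ± 0.274, and Arnt 16.3 ± 0.516. Nusap1 and Oip5 shared 1 promoter peak of 16.2 ± 0.984. Csnk1g1 and Trip4 shared another of 16.5 ± 1.84, and Hltf had 16.4 ± 1.53. Each SD is over 2 replicates.

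Of the transcription factors of the myeloid lineage, Spi1, Cebpa, Cebpb, Irf8 and Klf4 had open promoters and further open regions nearby. Of the 32 in the myeloid list, 27 had an open promoter and 28 had a distal region. Spi1, which encodes PU.1, lies on chromosome 2 from 91082390 to 91115756. Its promoter peak had a fold enrichment of 6.15 ± 0.273 (SD, n = 2), and 4 intronic regions were assigned to it. The intronic region from 91089074 to 91089623 had 4.78 ± 0.0156. The replicates' own thresholded sets gave Spi1 1 distal region each. Cebpa on chromosome 7 had a promoter peak of 7.64 ± 0.458 and 3 intergenic regions (1 and 2 in the own thresholded sets), the strongest of which, from 35098657 to 35099265 with its summit 20.4 kb upstream of the TSS, had 6.17 ± 0.184. Cebpb had 15 distal regions, against 11 and 10 in the replicates' own thresholded sets, and a weak promoter peak of 3.43 ± 0.044. The summit of the pooled promoter region lay 1.16 kb upstream of the Cebpb TSS, and the region did not reach the TSS. Irf8 had 6 distal regions and a promoter peak of 6.12 ± 1.08, and the replicates' own thresholded sets gave it 1 and 3 distal regions. Klf4 had 8 distal regions, against 3 and 5 in the replicates' own thresholded sets, and the strongest, on chromosome 4 from 55623262 to 55623810 and 91.1 kb upstream of the TSS, had 11.2 ± 0.495.

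Receptors that mark monocytes were open at varied sites. Csf1r, the receptor for the growth factor M-CSF, lies on chromosome 18. Its promoter peak, from 61105507 to 61106256, had 3.5 ± 0.404, below the 8.38 ± 0.481 of an intergenic region from 61098989 to 61099334, 6.43 kb upstream of the nearest start of a protein-coding transcript of the gene, and 5 distal regions were assigned to it (3 and 4 in the replicates' own thresholded sets). Cx3cr1, the fractalkine receptor, had 5 distal regions (4 and 3 in the own thresholded sets) and a promoter peak of 5.41 ± 0.0842. Ccr2 had no open promoter but 3 distal regions (2 in each own thresholded set), of which an intronic one on chromosome 9 from 124112615 to 124113029 had 11.0 ± 2.46. Tlr4, the receptor for lipopolysaccharide, had the strongest promoter among these genes, 10.7 ± 0.226. Ly6c2 had 6.59 ± 0.0876, Lyz2 6.69 ± 0.718, Cd68 5.69 ± 0.0818, Itgam 4.83 ± 0.135, Cd14 4.08 ± 0.545 and Ciita 4.15 ± 0.351. Fcgr1 had a promoter peak of 6.84 in the pooled set and a peak of its own in replicate 1 only. Nr4a1, a factor needed by nonclassical monocytes, had 8 distal regions, and Il1b had 6 with no open promoter, against 5 and 3 for Nr4a1 and 3 and 2 for Il1b in the replicates' own thresholded sets.

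**Figure D2:**
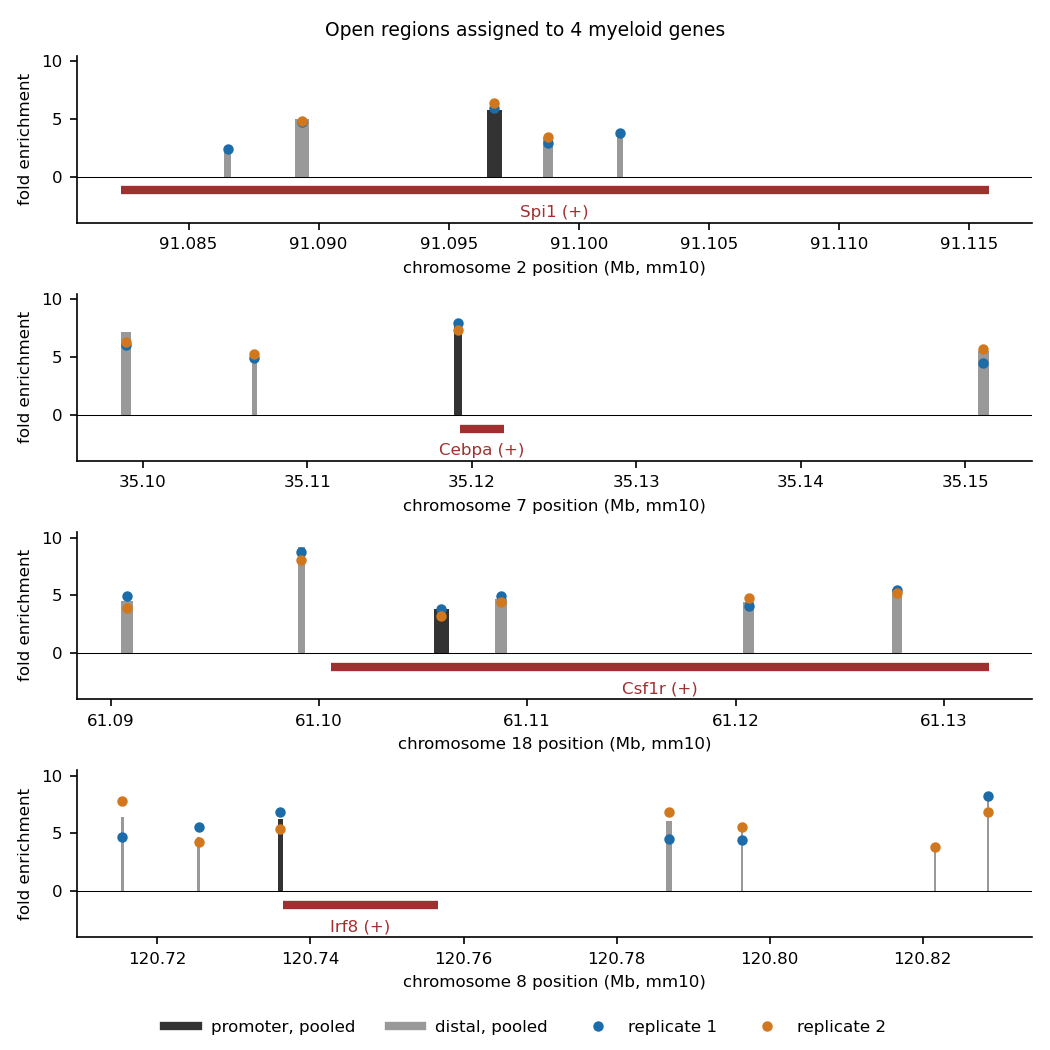
Open regions of the conservative set assigned to Spi1, Cebpa, Csf1r and Irf8, with position in Mb on mm10 along the x axis and fold enrichment on the y axis. Bars, drawn to the width of each region, are the pooled values (black at the promoter, grey distal), points are replicate 1 (blue) and replicate 2 (orange), and the red line is the gene. The Csf1r promoter, at a replicate mean of 3.5, is lower than the region 6.43 kb upstream of the nearest protein-coding TSS, at 8.38.

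Genes of other lineages were named for comparison. Gata1, Kit, Alb, Neurod1 and Myod1 had neither an open promoter nor a distal region. Cd3e and Bcl11b, T-cell genes, each had 1 distal region and no open promoter, and so had Ncr1, of natural killer (NK) cells, Elane, of neutrophil granules, and Itga2b, of platelets. The replicates' own pseudoreplicated sets, kept by a looser rule than the conservative set, did hold promoter peaks at Ncr1, of 7.15 and 4.23, and at Itga2b, of 3.49 and 2.64. S100a8 had no open promoter in the conservative set, though these looser sets gave 3.08 and 3.43. Pax5, a B-cell factor, had an open promoter of 5.13 ± 0.451 (SD, n = 2), and Klf1, an erythroid factor, had a promoter region on chromosome 8 from 84902890 to 84903634, with its summit 1.27 kb downstream of the TSS, of 4.83 ± 0.789. Neither replicate's own pseudoreplicated set held a region within 1 kb of the Klf1 TSS. The Klf1 value is that of replicate regions that overlap the pooled one. The housekeeping genes Gapdh and Actb had promoter peaks of 7.85 ± 1.05 and 3.81 ± 0.509.

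Of the genes with most distal regions, Foxp1, a transcription factor, had 19 distal regions and Zfp36l2, which encodes an mRNA-destabilising protein, had 18. Sgms1 had 17, and Ankrd44, Cmip, Nedd9, Rere and Zmiz1 had 16 each. Cebpb had 15, and Nfkbiz, Rubcnl and Smad3 had 14. B4galt5, Foxn3 and Ier5 had 13. These counts were not set against the length of the regulatory domain, which was 649 kb for Foxp1, 112 kb for Cebpb and 89.5 kb for Rubcnl. The replicates' own thresholded sets, which hold fewer regions, gave another order, with 9 and 8 for Foxp1, 11 and 12 for Zfp36l2, 11 and 15 for Sgms1, 9 and 9 for Ankrd44, 8 and 10 for Cmip, 11 and 10 for Nedd9, 8 and 6 for Rere, 9 and 10 for Zmiz1, 8 and 10 for Nfkbiz, 9 and 7 for Rubcnl, 11 and 11 for Smad3, 11 and 10 for B4galt5, 7 and 8 for Foxn3, and 8 and 6 for Ier5. Of 17849 distal regions, 16273 (91.2%) had a TSS within 100 kb, 7352 genes had at least 1, and 94 genes had 10 or more.

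Gene lists fixed from knowledge of blood cells were then compared with random lists matched on the length of their regulatory domain. Of 29 lists, 8 had more distal regions per gene than matched lists and 0 had fewer. At an unadjusted share under 0.05 these counts were 10 and 0. Myeloid transcription factors had 4.66 distal regions per gene, 4.69 times the matched mean of 0.992 (adjusted two-sided share among 10000 matched lists 9.67e-04), and 28 of 32 members had at least 1. Runx1 and Fli1 had 12 each. Nonclassical monocyte genes had 4.0 per gene, 5.17 times the matched mean, with 19 of 20 members at 1 or more; Nr4a1 had 8, Cd36 and Hes1 had 7 each, and Eno3 had no region. Fc and phagocytic receptors had 2.81 per gene (3.86 times), with Fcgr3 at 7 and Cd300a at 6, while Marco had none. MHC class II presentation had 1.86 (3.85 times), with Cd86 at 5. Innate sensors had 2.34 (3.33 times), with Aim2 and Nod1 at 8 each and Tlr8 at 0. Monocyte identity genes had 2.40 (3.14 times), with Emilin2 at 8 and Chil3 at 0. The replicates' own thresholded sets, which hold fewer regions, gave 9 and 8 for Runx1, 5 and 4 for Fli1, 5 and 3 for Nr4a1, 6 and 6 for Cd36, 6 and 7 for Hes1, 3 and 5 for Fcgr3, 6 and 5 for Cd300a, 3 and 3 for Cd86, 6 and 5 for Aim2, 3 and 4 for Nod1 and 4 and 6 for Emilin2. Each of these 6 lists had the same adjusted share, 9.67e-04, which rests on the smallest share 10000 lists can give, 2.00e-04. Cytokines and chemokines had 1.70 (3.06 times, adjusted share 0.0017), with Ccl6 at 8 (3 and 4 in the own thresholded sets), and dendritic cell genes 1.80 (2.37 times, 0.0196), with Id2 at 6 (4 and 3). The lists share genes, so the calls are not separate: 15 of 30 monocyte identity genes also stand in another list, as do 12 of 27 Fc and phagocytic receptors, 9 of 25 dendritic cell genes, 7 of 20 nonclassical monocyte genes, 6 of 32 myeloid transcription factors, 4 of 29 innate sensors, 2 of 30 cytokines and chemokines and 1 of 14 MHC class II genes. All 8 were higher in both replicates' own sets, which the rule for a call requires. The call for MHC class II ended under the stricter set and without matching, where the highest adjusted share was 0.119. Its ratio was 2.49 or more under each of 9 alternatives. Genes are not replicates, so these shares describe the libraries at hand. Neither these shares nor those for promoters below allow for neighbouring genes within a list.

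The other lists did not pass. The classical monocyte list had 1.35 distal regions per gene, 1.63 times the matched mean (adjusted share 0.336), with Ccr1 at 7 and F13a1 at 5 but Cd177 and Chil3 at 0. In the replicates' own thresholded sets Ccr1 had 0 and 2 and F13a1 had 3 and 3. Among lymphocytes the ratios were 1.82 for B cells (0.196), 1.73 for NK cells (0.160) and 1.01 for T cells (0.950). The NK list passed in the looser replicated set, at 2.58 times (0.0017), and so did the B-cell list, at 2.14 times (0.0329), the platelet list, at 2.02 times (0.0329), and the HOX list, with fewer regions, at 0.298 times (0.0238). Bach2 had 9 distal regions, against 2 and 5 in the replicates' own thresholded sets, Ralgps2 6 (5 and 4), Klrb1c 7 (6 and 5) and Ccr7 4 (4 and 3). Erythroid genes had 0.533 times the matched mean, neutrophil genes 1.55, platelet genes 1.72, mast cell, basophil and eosinophil genes 1.19, progenitor genes 0.905 and interferon response genes 1.4. Tissue-resident macrophage genes had 1.45, with Adgre1 and Hmox1 at 5 each and C1qa and C1qb at 0. In the replicates' own thresholded sets Hmox1 had 1 and 1 and Adgre1 4 and 2. Hepatocyte genes had 0.407, neuron genes 0.436, epithelial genes 0.427, muscle genes 0.62, endothelial and fibroblast genes 0.609, germ cell genes 1.08 and HOX genes 0.346. Ribosomal protein genes had 1.95, oxidative phosphorylation genes 1.42 and cell cycle genes 1.91; without matching the ribosomal ratio was 0.952 and that of oxidative phosphorylation 0.977. The ratios of T-cell, progenitor, germ cell and mast cell, basophil and eosinophil genes also crossed 1 under at least 1 alternative. The neuron list passed with fewer regions in the pseudoreplicated set, at 0.417 times (0.0416), and the ribosomal list with more in the stricter set, at 2.43 times (0.0435).

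**Figure D3:**
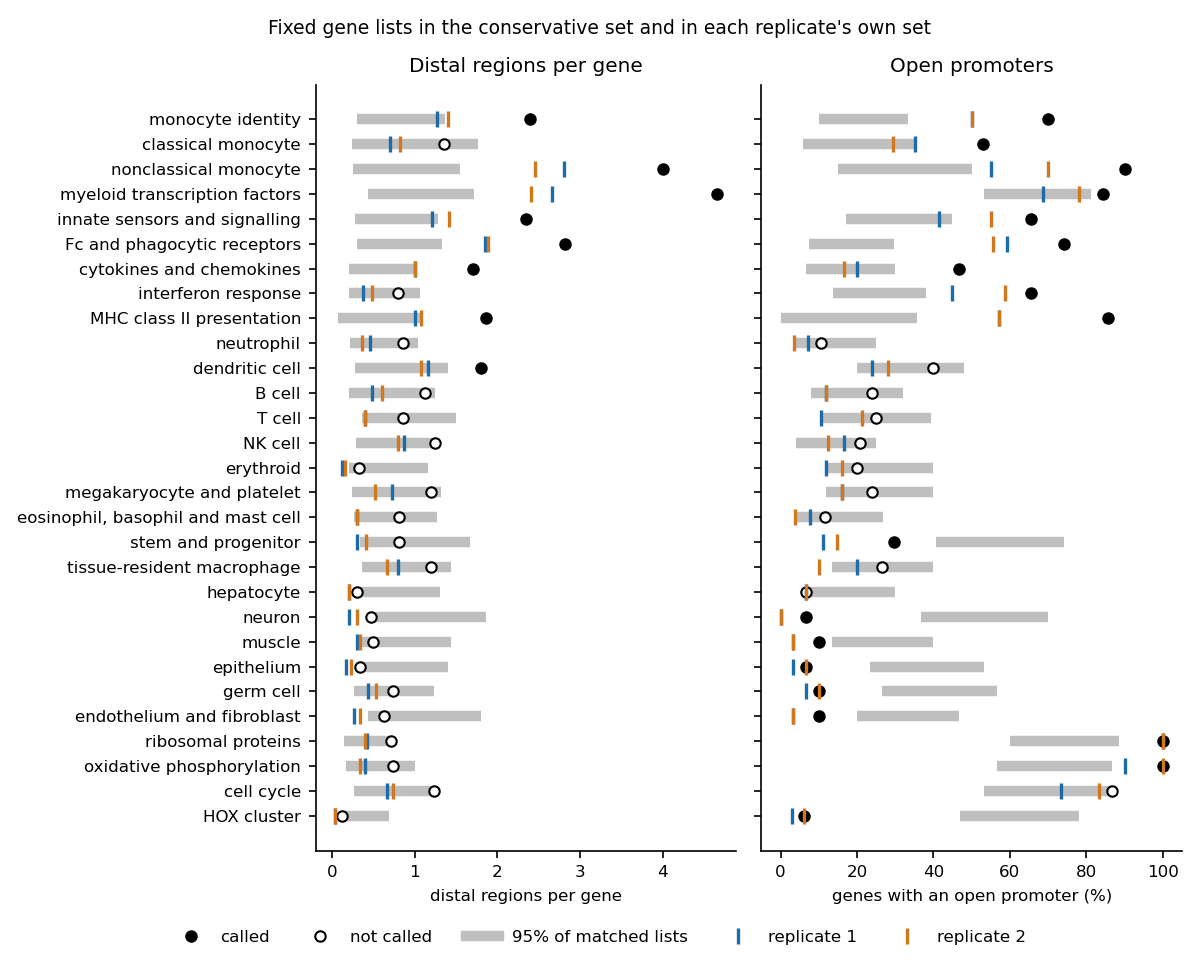
Each row is a fixed gene list, with distal regions per gene on the left and the percent of genes with an open promoter on the right. Circles are the conservative set (filled where called), grey bars hold 95% of its matched random lists, and ticks are the own sets of replicate 1 (blue) and replicate 2 (orange), which hold fewer regions. Myeloid transcription factors lie at 4.66 distal regions per gene and neuron genes at 6.67% open promoters.

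More lists were called for promoters, 18, than for distal regions, 8. Of these, 10 promoter and 7 distal lists were called under each alternative. With matching on promoter CpG, 11 lists had more open promoters than matched lists and 7 had fewer. MHC class II genes were open at 12 of 14 promoters (85.7%, 5.41 times the matched mean, adjusted share 5.27e-04), Fc and phagocytic receptors at 20 of 27 (74.1%, 4.44 times), monocyte identity genes at 21 of 30 (70.0%, 3.41 times) and nonclassical monocyte genes at 18 of 20 (90.0%, 2.83 times). Interferon response genes were open at 19 of 29 promoters (65.5%, 2.65 times), with 5.27e-04 in each of these lists, although the call for the interferon list ended without matching. Classical monocyte genes were open at 9 of 17 (52.9%, 3.01 times, 0.0012), and cytokines and chemokines at 14 of 30 (46.7%, 2.91 times), but both calls ended without matching and when the replicate 2 set stood alone, and the latter also with the replicate 1 set alone and in the other thresholded set of the series. Without matching on CpG the ratios of these lists were lower, at 1.84 for MHC class II, 1.59 for Fc and phagocytic receptors and 1.5 for monocyte identity. They were 1.93 for nonclassical monocyte, 1.41 for interferon response and 1.14 for classical monocyte genes, and 1.00 for cytokines and chemokines. Innate sensors were open at 19 of 29 (65.5%, 2.16 times), a call that ended with the replicate 1 set alone (1.71 times) and without matching (1.41 times). All 35 ribosomal protein promoters and all 30 of oxidative phosphorylation were open (1.34 and 1.37 times, and 2.15 times each without matching). Myeloid transcription factors were open at 27 of 32 (84.4%, 1.26 times, 0.043), but this call ended under 5 of 9 alternatives. The ratio was 0.753 in the stricter set and rose to 1.81 without matching.

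Promoters of unrelated tissues mostly held no region of the conservative set, which does not show that they were closed. In the replicates' own pseudoreplicated sets Acta2 had promoter peaks of 4.09 and 6.07, Elf3 of 4.87 and 3.32 and Dlx2 of 2.54 and 3.34. Alb, Neurod1 and Myod1 had none in these sets either. HOX genes had 2 of 32 open (6.25%, 0.101 times the matched mean), neuron genes 2 of 30 (6.67%, 0.124 times) and epithelial genes 2 of 30 (6.67%, 0.17 times), each with an adjusted share of 5.27e-04. Germ cell genes had 3 of 30 (0.243 times, 8.92e-04), endothelial and fibroblast genes 3 of 30 (0.31 times, 0.0023) and muscle genes 3 of 30 (0.38 times, 0.0496). Stem and progenitor genes had 8 of 27 (29.6%, 0.522 times, 0.0051). In the looser replicated set the ratios were 0.174 for HOX, 0.366 for neuron, 0.345 for epithelial and 0.464 for germ cell genes. The calls for endothelial and fibroblast, muscle and progenitor genes ended in that set, at 0.727, 0.559 and 0.845 times the matched mean, and in the pseudoreplicated set. The call for progenitors ended also without matching, and that for muscle also in the stricter set and with a 500 bp window. Blood lists that did not pass were neutrophil (3 of 28, 10.7%), B cell (6 of 25), T cell (7 of 28), NK cell (5 of 24, 20.8%), erythroid (5 of 25), platelet (6 of 25), mast cell, basophil and eosinophil (3 of 26, 11.5%) and dendritic cell (10 of 25). Tissue-resident macrophage (8 of 30), hepatocyte (2 of 30) and cell cycle (26 of 30) genes did not pass either. The NK list did pass in the replicated set, at 3.07 times the matched mean (4.46e-04), and so did the cell cycle list, at 1.21 times (0.033), and the hepatocyte list, with fewer open promoters, at 0.285 times (0.0329). The B-cell list had 2.46 times the matched mean there (4.46e-04), against 1.19 in the conservative set, but was not called because the replicates' own thresholded sets gave 0.782 and 0.744. Without matching on CpG the NK ratio turned from 1.5 to 0.447 (0.0272), that for T cells from 1.05 to 0.536 (0.042), that for B cells to 0.517 (0.048) and that for dendritic cells from 1.17 to 0.855. In the replicated set the neutrophil, erythroid and platelet ratios turned from 0.811, 0.807 and 0.898 to 1.62, 1.39 and 1.51. The tissue-resident macrophage list and the mast cell, basophil and eosinophil list crossed 1 under at least 1 alternative each.

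The last question was which transcription factor sites lay at the summits. In the 17849 distal regions the CTCF string CCMYCTRGTGG was the most concentrated: 7.55% of regions held it within 100 bp of the summit against 0.157% of flanks, a ratio of 48.1 (95% bootstrap interval 37.8 to 63.7), while the replicates' own sets gave 30.5 and 40.6. The PU.1 string GAGGAAGT was in 11.9% of distal summits, 8.82 times the flanks (8.01 to 9.80), and 9.09 ± 0.418 times in the replicates' own sets (SD, n = 2). The composite of ETS and IRF sites reached 2.52 (2.30 to 2.76), AP-1 2.48 (2.31 to 2.67), the NR4A string AAAGGTCA 2.52 (2.20 to 2.88), KLF 2.19 (2.02 to 2.36), CEBP 1.77 (1.68 to 1.85) and RUNX 1.74 (1.63 to 1.86). All intervals are over regions of the pooled set and do not measure the spread between replicates or peak sets. The replicates' own thresholded sets gave 2.54 and 2.70 for the composite, 2.70 and 2.72 for AP-1 and 2.96 and 3.28 for NR4A. They gave 2.44 and 2.58 for KLF, 1.95 and 1.86 for CEBP and 1.83 and 1.90 for RUNX. NFKB had 3.42 (2.49 to 4.74), in 0.594% of regions. Below the flanks were GATA at 0.705 (0.620 to 0.798), T-box at 0.76 (0.621 to 0.923), EBF at 0.739 (0.562 to 0.961) and homeobox at 0.447 (0.403 to 0.494). NRF1 reached 7.33, CRE 5.37, the GC-rich ETS string 4.93, EGR 2.90, MITF-TFE 2.17, SP 2.06, MEF2 1.94, E-box 1.49, the POU octamer 1.36, NFY 1.27 and the ISRE 1.24, and TCF-LEF was below the flanks at 0.788. The intervals of STAT, FOX, HNF4 and SOX held 1, and HNF1 was found at no summit. Against the permuted consensus in place of flanks, the GC-rich ETS string had 1.87 and CRE 2.16, MITF-TFE turned to 0.867, and TCF-LEF and EBF to 1.25 and 1.37. In all, 20 of 30 strings had an interval above 1, and 5 of those with at least 1 summit hit had an interval below 1.

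Of the 16 strings with an interval above 1 at promoters, 15 also had one above 1 in distal regions, with other ratios. In 10589 promoter regions, CRE reached 15.3 (11.7 to 21.2), the GC-rich ETS string CCGGAAGT 13 (10.9 to 15.9), NRF1 12.7 (8.49 to 21.4), SP 4.85 (4.44 to 5.26) and NFY 4.52 (4.26 to 4.84), the last in 23.2% of summits. PU.1 was lower at promoters, at 3.09 (2.66 to 3.56), as was CTCF, at 6.18 (4.53 to 8.78). CEBP and RUNX had intervals below 1 at promoters, 0.809 to 0.970 and 0.751 to 0.963. Of the strings with at least 1 summit hit, 9 had an interval below 1 at promoters. A string marks a family of factors and not a bound protein. T-box in distal regions had 1.13 in the replicated set, and at promoters CEBP had 1.86 and RUNX 1.43 against the permuted consensus.

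**Figure D4:**
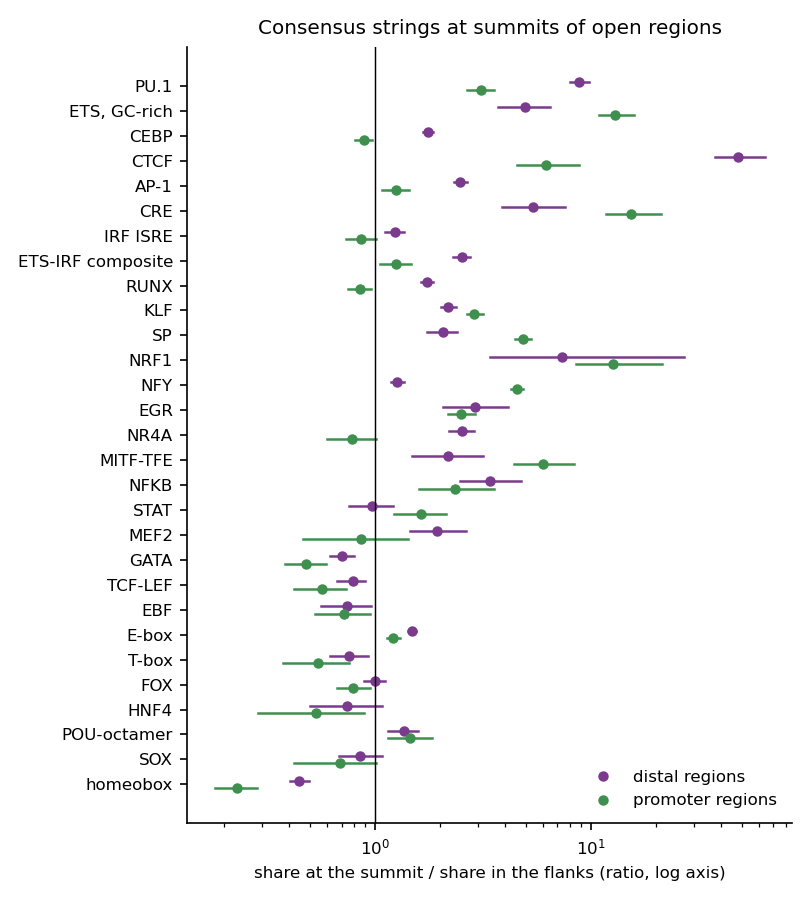
Ratio of the share of regions with a consensus string at the summit to the share in the flanks, on a log axis, with 95% bootstrap intervals over regions, for distal (purple) and promoter (green) regions. HNF1, with a ratio of 0, is not drawn. PU.1 lies at 8.82 in distal and 3.09 in promoter regions, and CRE at 5.37 and 15.3.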

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

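The tests of repeated sequence and of weak signal in this part were set before their results were seen. Peaks that passed the score minimum in a ranked list but are outside the matching thresholded set are a signal in data that the report does not use. There were 336 for the conservative set and 337 for the other thresholded set of the series, 201 for replicate 1 and 217 for replicate 2. Of the 336, 160 lay on unplaced contigs and 176 on chromosomes. The largest groups were 23 peaks on chromosome 9 from 2999966 to 3038289, 14 on chromosome 17 from 39843013 to 39848790, 13 on chromosome 14 from 19415723 to 19419719, and 12 on chromosome 1 from 24611560 to 24616165, all 12 with a summit sequence of the mitochondrial genome.

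One candidate explanation is sequence present more than once in the genome. The 40 bp at the summit occurred again in chromosomes 1 to 19, X and Y or in the mitochondrial genome for 52 of the 176 peaks (29.5%). Of 39944 kept peaks, 892 (2.23%) had such a summit. Repeated sequence could thus account for those 52 peaks. Only exact copies were sought, so copies that differ, or that lie elsewhere in the assembly, would be missed. The explanation is undecided for the other left-out peaks. Weak signal is not decided by the median: left-out peaks had a median fold of 4.44, between the lower quartile (3.96) and the median (5.62) of kept peaks, while their upper quartile of 8.77 exceeded the 7.59 of kept peaks. What the authors left out, and by which list, is not given in the sources used here and was not tested, and no biological explanation was tested.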

How the results depend on the processing

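No paired analysis was possible because the series has a single group. The number of accessible regions was 55857 in the replicated, 52671 in the pseudoreplicated and 18764 in the stricter set, and 17604 to 18057 with a replicate left out. Shares found in the other replicate were 73.5% and 72.9% with reciprocal overlap, 82.2% and 80.1% in the own thresholded sets, 83.4% and 81.6% at or above the median fold, and 84.8% and 85.2% with equal numbers of strongest peaks. The correlation was 0.898 for −log10 p, 0.844 for thresholded sets, 0.866 at promoters and 0.788 at distal sites. The share of regions at promoters was 26.9% (replicated), 28.1% (pseudoreplicated), 42.7% (stricter), 34.7% (500 bp), 40.7% (2 kb), 44.0% (all annotated genes) and 47.2% to 47.9% with a replicate left out. Lists with fewer distal regions numbered 1 (replicated), 2 (pseudoreplicated) and 1 (no matching); with fewer open promoters 4 (pseudoreplicated) and 13 (no matching). Of lists called, 7 of 8 (distal) and 10 of 18 (promoter) were called under each of 9 alternatives. Over the single lists, 14 promoter and 11 distal results passed under an alternative and not in the conservative set, and 133 motif ratios moved beyond the replicate spread without turning. Among promoter lists the ratio crossed 1 in 10, of which 9 were not called: myeloid transcription factor (0.753), dendritic cell (0.971), T-cell (0.937) and tissue-resident macrophage (1.03) genes in the stricter set; NK (0.447), B-cell (0.517), T-cell (0.536) and dendritic cell (0.855) genes without matching; neutrophil (1.62), erythroid (1.39) and platelet (1.51) genes in the replicated set; the same 3 (1.67, 1.42 and 1.30) and tissue-resident macrophage genes (1.18) in the pseudoreplicated set; the latter in the other thresholded set (1.10); dendritic (0.969) and T-cell (0.802) genes at 500 bp; neutrophil (1.35), mast cell, basophil and eosinophil (1.08) and tissue-resident macrophage (1.02) genes at 2 kb; and, with a replicate left out, dendritic (0.834 to 0.939), B-cell (0.749 to 0.782) and T-cell (0.575 to 1.11) genes. Among distal lists it crossed 1 in 6, none called: germ cell (0.885) and progenitor (1.14) genes in the replicated and 0.811 and 1.30 in the pseudoreplicated set, germ cell genes in the other thresholded set (0.966), T-cell genes at 50 kb (0.98), T-cell (0.915), progenitor (1.14) and germ cell (0.968) genes with no distance limit, germ cell (0.992), progenitor (1.10), ribosomal (0.952) and oxidative phosphorylation (0.977) genes without matching, and T-cell (0.886 to 0.895) and mast cell, basophil and eosinophil (0.864 to 0.865) genes with a replicate left out. Among strings whose interval excluded 1, direction turned for T-box in distal regions (1.13 replicated, 1.10 pseudoreplicated) and for motif AP-1 in promoter regions (0.985, stricter). With the permuted consensus it turned for MITF-TFE (0.867), TCF-LEF (1.25) and EBF (1.37) in distal regions. In promoter regions it turned likewise for CEBP (1.86), RUNX (1.43), TCF-LEF (1.16), FOX (1.70) and HNF4 (1.55). Among strings whose interval held 1, some ratios below 1 rose above it with the permuted consensus. These were HNF4 (1.48) and STAT (1.23) in distal and the ISRE (2.34), NR4A (2.11) and MEF2 (2.40) in promoter regions. The cause was not tested. Unknown depth limits what weak regions can show.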

Other observations

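The tests on regions of a single replicate in this part were chosen after their results were seen, and the dendritic cell list without shared genes was a setting added after seeing the data, with its outcome read as open only once it was seen to fall on the limit. Open regions were unevenly spread over chromosomes. Chromosome 11 had 19.5 regions per Mb, chromosome 19 had 16.5 and chromosome 17 had 15.9, against 8.11 on chromosome 18 and 3.05 on X. The Y chromosome had 18 regions. The median distal summit lay 17.7 kb from the nearest TSS.

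Among the 20 strongest kept peaks, with folds of 19.1 or more, 9 had a summit sequence that occurs again in the reference and 4 had 1 of the mitochondrial genome. The strongest lay on chromosome 2 from 69355473 to 69355727 and was one of those 4. The promoter peak of Golph3l, on chromosome 3 from 95588544 to 95589193 with a pooled fold of 19.4, is among the 20, and its summit sequence occurs once.

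Regions called in a single replicate may be regions near the calling threshold. Of those of replicate 2, 94.9% lay below the median −log10 p of that replicate's regions, and of those of replicate 1, 95.2%. Below the median, −log10 p ran from 2.02 to 12.6 in replicate 1 and from 2.05 to 13.6 in replicate 2. These regions were thus mostly among the weaker ones, but how near the threshold they lay was not measured. Also, 69.5% of those of replicate 1 and 69.4% of those of replicate 2 overlapped the replicated set of the series. A set of strong regions present in a single replicate is argued against, since in the strongest of 4 classes of equal size 0.0809% of replicate 1 regions and 0.01% of replicate 2 regions were absent from the other replicate. No biological explanation was tested.

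The dendritic cell list had more distal regions than matched lists, and 9 of its 25 genes also stand in other lists. The 16 genes in no other list had 2.07 times the matched mean, exactly at the upper limit of 95% of matched lists, with a share of 0.0568, so shared genes may or may not account for the call. In replicate 1's own set they had 2.66 times (upper limit 2.36, share 0.0268), and in replicate 2's 2.30 times, on its limit (share 0.0618).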
